A study of Alternanthera philoxeroides with 2 samples.

How the data were processed

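RNA sequencing was carried out on total RNA from roots of alligator weed (Alternanthera philoxeroides), per the labels' protocols. Plants raised for 10 days in hydroponic solution were divided, and one part was moved for 7 days to a solution without potassium sulfate while the other stayed in full solution. The groups may thus also differ by the move itself and by sulfate, and these were not separable from potassium supply. The series holds 2 libraries, 1 per condition, so there was no replicate spread and no test between conditions was possible. No p-value was computed here. The reads were assigned to unigenes of a de novo assembly, per the series title. The assembler, the aligner, the counting program and their versions are not given in the sources used here.

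The authors deposited a table of 64763 unigenes with raw fragment counts in each library, and the column totals equal those printed in the file headers. The same table holds FPKM values that the authors computed as fragments per kilobase of unigene and M fragments of the library; all 129526 FPKM values were recomputed from fragments, length and total within 0.0001. It also holds the authors' log2 ratio, a p-value and an FDR for each unigene, from a test that no header or label names. In all 2972 unigenes at 0 in one library, the deposited log2 ratio equals, within 0.001, the ratio with 0 replaced by 0.001 FPKM, so those ratios are set by the stand-in. The deposited FDR equals a Benjamini-Hochberg adjustment of the p-value column within 1% for all 64763 unigenes. A coverage table per library gives the number of reads (single mates, about 90.0 bases each) with a unique or a multiple placement as counts, the mean depth of coverage, and the percent of the unigene length covered and of G and C bases, per the file headers. The files identify unigenes by ID and do not pair them with gene names, so the planned gene lists could not be used and functions are not discussed. No reference genome or annotation was used here.

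The fragment counts were used as the main measurement. This departs from the plan, which named the per-library tables. Those count single mates and can count a read with several hits at each, so their uniquely mapped reads served as an alternative. In 3036 unigenes of the control and 2917 of the low-potassium library the fragments outnumber the unique reads, so the fragment counts include some with several hits. Each ratio compares fragments as a share of the library total, low potassium over control, with an exact 95% interval (Clopper-Pearson on the share of one library in the sum, converted to a ratio). Such intervals cover counting error only; fragments without molecular identifiers are not independent molecules, and the intervals hold nothing of the spread between plants. A unigene without fragments in one library was given the bound against a floor of 3 fragments in that library, and counts and medians of ratios hold it at that bound. The bound takes the count of the other library as it stands; the 2-sided exact interval is stricter and starts lower, at 193-fold, 141-fold and 91.0-fold for the 3 named unigenes with bounds of 238-fold, 174-fold and 112-fold. Unigenes with 20 fragments or more over both libraries (55661) were examined, and a ratio of at least 2-fold either way was counted as higher or lower. The rule for naming unigenes ranked those with 100 fragments or more by the interval bound nearer to no difference, or by the floor bound where one library had none, and took the first 2 in each direction.

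The step was tested on simulated Poisson counts drawn from the pooled means and the real totals. They hold no spread between plants or library preparations. Unchanged unigenes were drawn around no difference by library totals, while the real median log2 ratio lay at 0.39. The shares counted below by counting error alone may therefore be too small for the real libraries. Of 100 unigenes changed by 1.5 on the log2 scale 95.0% were found, and of 100 changed by 3 all were. Of 55029 unchanged unigenes 2.21% were counted as at least 2-fold different by counting error alone, and the interval held the true ratio in 96.1%. The interval rests on the same counting model, so that share does not test it on real libraries. Among 26526 unchanged unigenes with 100 fragments or more, 0.00377% were counted.

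The comparisons, the gene lists, the naming rule and the following alternatives were fixed before the data were examined. The alternatives were TMM, median-ratio and upper-quartile scaling, other fragment minimums, a 4-fold limit, a limit on the whole interval, thinning of the control library to the total of the other, FPKM with a pseudocount of 0.1 or 1, and the authors' own FDR. Uniquely mapped reads became an alternative when the fragment counts took their place. Library totals without the 2 most abundant unigenes, a limit on GC content and a limit on ID numbers were added after the data were seen. The ID numbers of single unigenes were parted at 2 breakpoints by least squares on log2 ratios limited to ±3, on a grid of 50 numbers. For contigs that share a cluster number, ratios were reassigned 1000 times among contigs within deciles of fragment number. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and TMM factors came from edgeR 4.0.16 in R 4.3.3; edgeR was used for no test.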

Results

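Root transcripts of alligator weed, an aquatic and terrestrial weed of the amaranth family, were compared between 2 groups of plants. One was kept in full nutrient solution. The other was moved for 7 days to a solution without potassium sulfate, and is called low-potassium or potassium-deprived below. The control library held 18.9 M fragments and the low-potassium library 16.2 M. Both were assigned to 64763 de novo assembled unigenes of 200 to 7568 bases, with a median length of 417 bases and a median GC content of 41.6%. Of these, 26027 carried a cluster and contig number and 38736 a single number. Each condition had 1 library, so every difference below is one between 2 libraries without a replicate check, and the intervals give counting error alone.

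The first question was which transcripts made up each library. A pair of transcripts took a larger part of the library in roots kept in full solution than in potassium-deprived roots. The unigene with the most fragments, of 4682 bases and 54.9% GC, took 21.0% of all control fragments (exact 95% interval 20.9 to 21.0) and 7.13% of the low-potassium fragments (7.12 to 7.14). It was thus 2.94-fold lower under low potassium (2.93 to 2.95). The next, of 1681 bases and 54.7% GC, took 6.47% and 3.27%, a 1.98-fold lower share (1.97 to 1.98). Together they held 27.4% of the control and 10.4% of the low-potassium fragments. By FPKM, which corrects for length, their joint share was 8.76% and 3.12%. They ranked 1 and 2 by FPKM in the control, and 3 and 2 in the low-potassium library. Both were also lower with TMM scaling, at log2 ratios of -1.95 and -1.38. They were singled out after their values were seen. Their sequences were not analysed here, and ribosomal RNA was not excluded, so these shares are shares of assigned fragments and may not be shares of messenger RNA. The 100 most abundant unigenes held 42.1% of control fragments (42.07 to 42.11) and 27.1% of low-potassium fragments (27.10 to 27.14). Of the 100 in each library 78 were in both lists. Among the 122 in either list, 14 were at least 2-fold higher and 12 at least 2-fold lower under low potassium by library totals. With TMM scaling, which centres the bulk of unigenes near no difference, these numbers were 8 and 23.

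Most unigenes were found in both libraries. At 1 fragment or more, 62576 were detected in control roots and 63978 in potassium-deprived roots, with 61791 in both. Fragments were assigned in the low-potassium library alone for 2187 unigenes and in the control library alone for 785. Of these, 191 and 166 did have reads with several hits placed in the other library, and 0 had a unique read there. With 20 fragments or more the numbers were 744 and 263, of which 11 and 1 had such reads. Such a unigene with 20 fragments was at least 7.78-fold higher in the low-potassium library, or at least 5.71-fold higher in the control library, against a floor of 3 fragments in the library where it had 0. Both sets were short and GC-rich beside the whole assembly. The 744 had a median length of 342 bases and a median GC content of 50.3%, and the 263 had 351 bases and 50.2%. Across the 61791 unigenes found in both libraries, log2 FPKM had a Pearson correlation of 0.75, which is across unigenes and not across independent samples.

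The main question was which transcripts differed between deprived and supplied roots. By library totals, 12209 of 55661 unigenes (21.9%) were at least 2-fold higher under low potassium and 3354 (6.03%) at least 2-fold lower. Of the unigenes counted, 78.4% were therefore higher. The median unigene lay 0.39 above no difference on the log2 scale, with medians from 0.51 at 20 to 49 fragments to 0.35 at 1000 fragments or more. TMM scaling added -0.40 to every log2 ratio, the median was -0.01, and the numbers became 8306 higher and 5687 lower, so that 59.4% of those counted were higher. When the whole counting interval had to lie beyond 2-fold, 5781 unigenes were higher and 1439 lower. In the authors' deposited table, the word Up marks 47085 unigenes (72.7%) and the word Down 17678. At a deposited FDR of 0.001 or less with a 2-fold ratio, the authors' deposited table holds 9253 unigenes as Up and 2138 as Down; 8049 and 1987 of these were also counted here. That FDR compares 2 libraries and not the conditions.

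**Figure D1:**
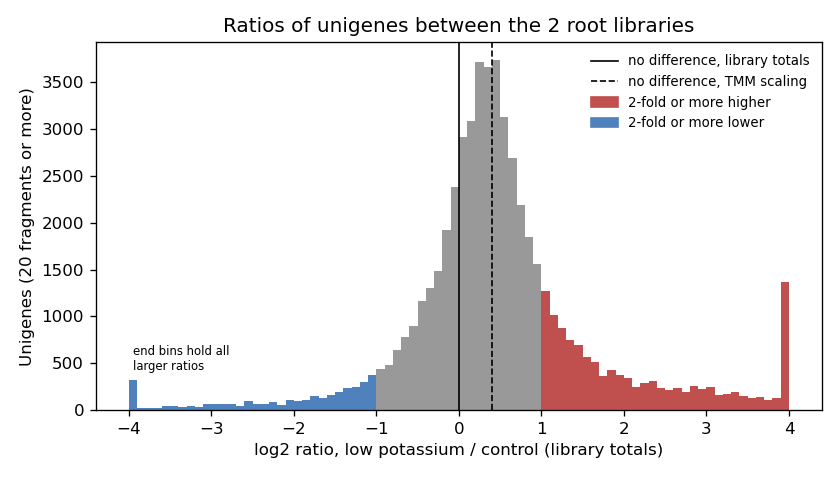
Number of unigenes with 20 fragments or more (y axis) by log2 ratio of low potassium over control, scaled by library totals (x axis), for the 1 control and 1 low-potassium library; the end bins hold all larger ratios, and a unigene at 0 in one library stands at its floor bound. The bulk of unigenes sits to the right of the solid line of no difference and around the dashed line, where TMM scaling places no difference, 0.40 higher.

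The unigenes at the ends of the ranking had nearly all fragments in one library. Unigene29070_All, of 381 bases and 33.9% GC, had 1 fragment in control roots and 6459 in potassium-deprived roots (0.139 and 1045 FPKM), a ratio of 7542-fold with a counting interval from 1353-fold to 297938-fold. With TMM scaling the ratio was 5730-fold. Unigene32963_All, of 3065 bases and 56.7% GC, had 612 fragments under low potassium and 0 in the control. By library totals and the floor of 3 fragments it was at least 238-fold higher and with TMM scaling at least 181-fold. In the other direction, Unigene21760_All, of 409 bases and 33.7% GC, had 609 fragments in control roots and 0 under low potassium. By the same floor it was at least 174-fold lower by library totals and 229-fold with TMM scaling. Unigene22277_All, of 377 bases and 42.2% GC, had 394 and 0 fragments. It was at least 112-fold lower by library totals and 148-fold with TMM scaling. Low-potassium fragments covered 94.8% of the length of Unigene29070_All and 99.7% of Unigene32963_All. Control fragments covered 97.3% of Unigene21760_All and 99.7% of Unigene22277_All. The files do not pair these IDs with gene names. Both higher ones have ID numbers above 25650 and both lower ones have numbers between 19950 and 25650, ranges in which most unigenes with 20 fragments or more in that library alone lie.

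GC-rich unigenes differed between the libraries more often than those of middle GC content. Under 35% GC, 22.7% of 4078 unigenes were at least 2-fold higher and 9.22% at least 2-fold lower, so both shares were also larger at the low end than at 40 to 45%. Of 24214 unigenes with 40 to 45% GC, 14.3% were at least 2-fold higher and 3.85% at least 2-fold lower under low potassium. At 50 to 55% GC the shares were 49.1% and 12.2% of 2839 unigenes. At 60% GC and over they were 69.7% and 17.8% of 1451 unigenes. The median log2 ratio was 0.35 at 40 to 45% GC, 1.71 at 55 to 60% and 1.94 at 60% and over. Under 35% GC, TMM scaling gave 12.9% higher and 15.7% lower, so the excess of higher unigenes was absent there. With TMM scaling 8.30% of unigenes at 40 to 45% GC and 61.8% at 60% and over were higher. Among unigenes with 100 fragments or more the shares higher were 7.97% and 71.7%. The shares lower there did not follow the order of GC content at its upper end, with 2.18% at 40 to 45%, 13.6% at 50 to 55%, 15.4% at 55 to 60% and 10.7% at 60% and over. Unigenes of 55% GC or more were 4.87% of those examined. Leaving out the 2 most abundant unigenes, they held 0.871% of control fragments and 1.40% of low-potassium fragments. Those 2 unigenes, both lower under low potassium, lie at 50 to 55% GC. Without them that class held 2.20% of control and 2.11% of low-potassium fragments, so its fragment share was not higher under low potassium.

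**Figure D2:**
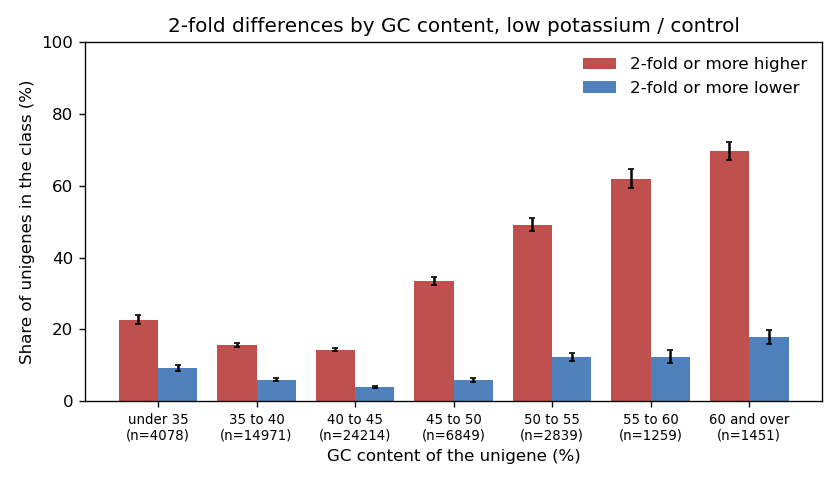
Share of unigenes with 20 fragments or more (y axis, percent) that were at least 2-fold higher or lower under low potassium, by GC content of the unigene (x axis, percent) with the number in each class; error bars are exact 95% binomial intervals over unigenes, which are not independent replicates. The share higher is 22.7% under 35% GC, smallest at 14.3% at 40 to 45% and 69.7% at 60% and over.

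Unigenes that were short or had few fragments differed by 2-fold more often than long or abundant ones. The length is that of the assembled unigene and may not be that of the transcript. Counting error alone also passes 2-fold more often at few fragments. In simulation around no difference it did so in 2.21% of unchanged unigenes, and in 0.00377% of those with 100 fragments or more. Among unigenes with 20 to 49 fragments, 34.4% were higher and 9.83% lower, against 8.94% and 3.61% among those with 1000 fragments or more. With TMM scaling the shares were 25.5% and 15.9% in the first class and 4.42% and 6.65% in the second, where lower unigenes then outnumbered higher ones. In the quartile of shortest unigenes, up to 303 bases, 27.6% were higher and 8.34% lower. In the next quartiles the shares were 29.4% and 7.66%, then 21.2% and 5.28%. In the quartile of longest unigenes, over 938 bases, they were 9.48% and 2.81%. With TMM scaling the longest quartile held 4.94% higher and 5.24% lower unigenes, so the excess of higher ones there was absent. These differences were not separated from those by ID number described below. Single unigenes numbered from 19950 to 25650 had medians of 34 fragments and 289 bases, and those with higher numbers 33 and 307. The medians were 99 and 455 for those numbered up to 19950, and 177 and 795 for clustered contigs.

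Contigs that share a cluster number differed in opposite directions less often than in random reassignments, by library totals. Among 7981 clusters with at least 2 examined contigs, 108 held both a contig at least 2-fold higher and one at least 2-fold lower. Reassigning the ratios among contigs of like abundance gave a mean of 196 such clusters and a range of 150 to 230 in 1000 draws. In 580 clusters at least 2 contigs were higher and none lower, and in 152 at least 2 were lower and none higher. These 2 numbers have no random expectation beside them, so they do not by themselves show agreement within clusters. Reads shared by near-identical contigs were not separable here: 45.6% of read placements in the control and 49.5% in the low-potassium library came from reads with several hits.

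The ratio of a single unigene went with the number in its ID. Among 19702 unigenes numbered up to 19950, 15.2% were higher and 3.28% lower, close to the 12.6% and 4.08% of the 23723 clustered contigs. Of 3956 unigenes numbered from there to 25650, 2.68% were higher and 43.4% lower, with a median log2 ratio of -0.78. Of 8280 unigenes numbered above that, 73.8% were higher and 0.290% lower, with a median of 1.89. The upper range held 6110 of the 12209 higher unigenes and the middle range 1715 of the 3354 lower ones (51.1%). Outside those ranges, 5993 unigenes were higher and 1615 lower by library totals. With TMM scaling the same 43425 unigenes gave 3090 higher and 3339 lower. The breakpoints and these counts were chosen after the data were seen.

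**Figure D3:**
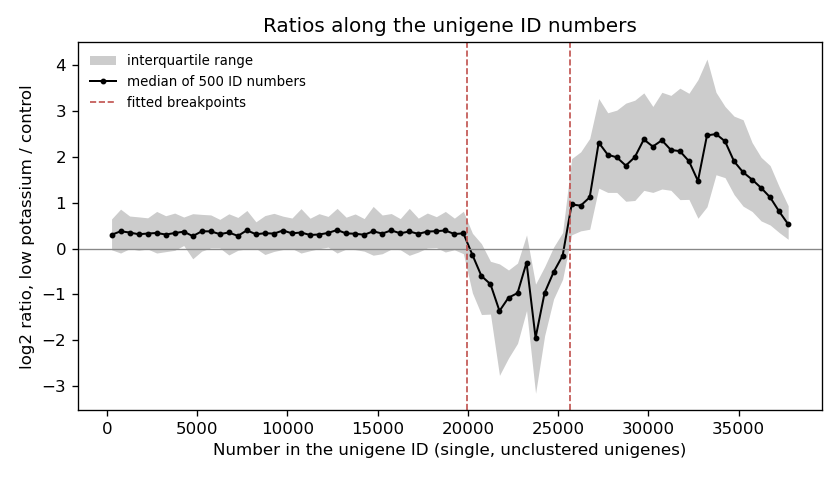
Median log2 ratio of low potassium over control (y axis, black line) and interquartile range (grey) of single unigenes in bins of 500 ID numbers (x axis), with the fitted breakpoints at 19950 and 25650 (dashed). The median is flat up to the first breakpoint, below 0 between the breakpoints and above 0 beyond the second.

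Breadth of coverage was high in both libraries. In unigenes with 10 to 99 uniquely mapped reads, the median covered length was 96.6% in the control (interval of the median 96.6 to 96.7) and 97.2% in the low-potassium library (97.2 to 97.3). With 1 to 9 such reads it was 77.9% (77.3 to 78.7) and 86.6% (85.9 to 87.1). With 100 or more it was 99.01% and 99.2%.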

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

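The look at unigenes outside the fragment table was chosen only after the tables were seen. The coverage tables list 186 unigenes that the fragment table leaves out, and these stand out because reads were placed on them in both libraries above the limit that a count of 0 allows. None of the 186 has a uniquely mapped read. In the control library 176 of them have more than 3 placements of reads with several hits, with a median of 93.0 and 39980 in all, and in the low-potassium library 182 have more than 3, with a median of 107.5 and 45599 in all. No group held enough libraries to look for a library far from the others, and with 1 contrast no difference between contrasts was available.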

How the results depend on the processing

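The totals without the 2 most abundant unigenes and the limits on GC content and ID numbers were chosen only after the results were seen. Of 73 alternative values 42 stayed close and 31 moved. The balance of higher over lower unigenes turned under one of them: 78.4% of those counted were higher by library totals, and 48.1% with TMM scaling outside the upper ID ranges. The number higher stayed within 1.5 times of 12209 under TMM, median-ratio and upper-quartile scaling, but the 3354 lower ones became 5687, 5737 and 5707. The shift follows from the construction of these scalings, which centre the bulk of unigenes. Fewer unigenes were counted with a minimum of 100 fragments (3499 higher, 1004 lower), a 4-fold limit (5342 and 1371), the whole interval beyond 2-fold (5781 and 1439) and the authors' FDR (9253 and 2138, of which only the second differs by over 1.5 times). The limit to unigenes outside the upper ID ranges gave 5993 and 1615, and with TMM scaling 3090 and 3339. The other settings for these counts, including thinning, uniquely mapped reads and either pseudocount, stayed within 1.5 times, as did every number of unigenes with fragments in a library or in it alone. The share of the control library in its 100 most abundant unigenes was 28.8% by FPKM, 32.3% for 10 and 60.05% for 1000 unigenes; for the low-potassium library these were 22.7%, 15.8% and 48.8%. Covered length with 1 to 9 unique reads was 77.2% and 85.2% over unigenes found in both libraries. With 100 fragments or more, the shares higher from the shortest to the longest quartile were 19.5%, 19.0%, 16.1% and 8.72%, the shares lower in the quartiles between were 4.81% and 4.22%, and 30 clusters held opposite contigs, against a random mean of 58.1 (37 to 78). The 4 named unigenes kept their direction under the 3 scalings, and 9 of these 12 ratios stayed within the counting interval. Beyond the scalings, stricter limits and smaller or larger sets, the cause of these shifts was not tested. The gene lists were not run because the files give IDs without names. Depth limits the rare unigenes: in unchanged unigenes simulated with counting error alone 2.21% passed 2-fold, nearly all with under 100 fragments. These were centred on no difference by library totals, while the real median log2 ratio was 0.39. The 2.21% is thus not the share of real unigenes that counting error carried past 2-fold. No paired analysis was possible because each condition had 1 library.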

Other observations

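The tests of the 2 dominant unigenes and of the spread at high GC were chosen only after those results were seen, as were the GC classes, the ID ranges and the counts outside those ranges.

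Unigenes with fragments in one library alone were as GC-rich in one direction as in the other. Of the 744 with 20 fragments or more, all in the low-potassium library, 52.0% had a GC content of 50% or more, and of the 263 with all fragments in the control 52.5%. Cluster contigs were 14.5% and 20.2% of these sets. The numbered ranges held most of them: 636 of the 744 lay in the upper range and 210 of the 263 in the middle range.

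The first pattern is the general excess of higher unigenes, a median log2 ratio of 0.39. It may follow from the fragments that the 2 most abundant unigenes took in the control library, since with both left out of the totals the median is 0.0831 and the counts become 8997 higher and 4948 lower. Their GC contents lie at percentiles 95.05 and 94.9 of the unigenes examined, and their log2 ratios, -1.56 and -0.98, differ by 0.57. Their sequences were not analysed here, so what they are stays open. An effect of potassium supply on the amount of RNA of either kind was not tested and stays open, since relative counts hold no absolute scale.

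The second pattern is the excess of GC-rich unigenes among those higher under low potassium. Unigenes of 55% GC or more were also more often lower, at 15.3% beside 3.85% at 40 to 45%, though 66.2% of them were higher. Unequal recovery of GC-rich fragments would move a GC class together. With 100 fragments or more the interquartile range of log2 ratios at 55% GC or more was 2.81 (2.56 to 3.08 in bootstrap draws). It was 5.34 times the 0.53 at 40 to 45%, which argues against unequal recovery as the whole cause. A wide spread cannot exclude a common shift beside it. The medians of these unigenes did rise, from 0.34 at 40 to 45% to 1.12 at 55 to 60% and 1.70 at 60% and over. Unequal recovery as a part of the cause therefore stays open. Assembly from one library alone was examined outside the middle and upper ID ranges. Of 1024 unigenes with 55% GC or more there, 55.4% (52.3 to 58.4) were higher, 5.81 times the 9.52% (9.13 to 9.93) at 40 to 45%. The shares lower were 6.35% and 2.48%. The excess was thus not confined to those ranges. This cannot decide on assembly from one library, since the ranges were fitted to these ratios. Whether they mark such assembly is left open below. A hypothesis that stays open is RNA of other organisms on or in the roots. Unigenes of 55% GC or more carried cluster IDs 0.473 times (0.432 to 0.515) as often as those at 40 to 45% of like length and abundance. This lies under the limit of 0.5 set beforehand, but the interval crosses that limit. The demand that it should not was added after the value was seen. Unigenes of the middle and upper ID ranges carry no cluster ID by definition. Of 2710 unigenes with 55% GC or more, 1024 lay outside those ranges, beside 20708 of 24214 at 40 to 45%. The share of cluster IDs therefore overlaps with the pattern by ID number and cannot decide on other organisms. RNA of other organisms cannot be told apart from a response of the plant's own GC-rich genes to the treatment, because no sequence or annotation was used here. Such a response was not tested.

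The third pattern is the order of ratios along the ID numbers. Counting noise in rare unigenes is argued against, because with 100 fragments or more 58.3% (54.9 to 61.7) of the upper range was higher, 4.97 times the 11.7% (11.3 to 12.1) of the lower range and the clustered contigs. The ranges were fitted to ratios that include those of these unigenes, and the intervals do not allow for that choice. A candidate explanation is that the middle and upper numbers were given to unigenes assembled from the reads of one library alone. At 10 to 29 unique reads in each library that differ by at most 20%, the median difference in covered length, low potassium minus control, was 2.13 percentage points in the upper range (0.99 to 2.80), -1.77 in the middle range (-2.56 to -0.80) and 0 elsewhere. Both directions are those this explanation calls for, but the smaller shift of 1.77 lies under the limit of 2 set beforehand. Reads with several hits may add to covered length and were not matched, so unequal numbers of them could also shift it. Assembly from one library and a response to the treatment therefore cannot be told apart for these unigenes, and the 2 do not exclude each other.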
